A study of Mus musculus with 2 samples.

How the data were processed

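RNA from primary mouse chondrocytes was sequenced in 2 libraries, 1 treated with PBS and 1 treated with recombinant mouse Sparcl1 protein (50 ng/ml, 3 days). Per the labels' protocols, total RNA was taken and libraries were made with a NEBNext Ultra RNA kit for a NovaSeq instrument. The authors deposited a table of counts, whole numbers of reads per gene symbol, with 1 column per library, and its columns were matched to the libraries by name. Per the submitters' processing notes, Trimmomatic, FastQC, STAR and HTSeq were used with genome build mm10. Their versions, the gene annotation, the strand setting and the treatment of reads with several genomic matches were not given in the sources used here. A kit or counting step that does not keep strand cannot separate overlapping genes on opposite strands. Genes with many near-identical copies can lose reads when those with several matches are discarded: Gapdh, a glycolytic enzyme with many pseudogenes, had 200 and 235 counts, while Aldoa of the same pathway had 26475 and 27267.

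The table had 21983 genes, of which 21900 (99.6%) were matched by symbol to the GENCODE M21 annotation of GRCm38, the assembly that mm10 names. Coordinates, exon lengths and GC content come from that annotation, and 99.6% of measured genes had a length and a GC value. In 26 entries the symbol had been turned into a calendar date, as spreadsheet programs do with certain gene names. They held 0.192% and 0.177% of the counts, stayed in the totals and are not named. Predicted or clone names made up 2203 entries, and 5899 genes had no count in either library.

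Library totals were 29858851 (control) and 26871933 (Sparcl1-treated). Counts were scaled to CPM, counts at a common library size, with factors from the trimmed mean of M-values (TMM), 0.988 and 1.01, from edgeR 4.0.16 in R 4.3.3. Everything else used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. With 1 library per group there is no estimate of the spread between cultures, so no test across libraries was made and no p-value is given. Each gene has the log2 ratio of its CPM, Sparcl1-treated over control, with an exact 95% Clopper-Pearson interval on the treated library's part of the gene's counts. The intervals treat reads as independent, cover counting error only and compare the libraries, not the conditions. Sequencing reads amplified by PCR without molecular identifiers are not independent molecules, so the intervals may be too narrow even for counting error. For a gene at equal expression, the upper bound lay 1.42 above the log2 ratio at 20 summed counts, 0.41 at 200 and 0.13 at 2000, so abundant genes are far better fixed than rare ones.

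A gene was called higher or lower with at least 20 summed counts, a log2 ratio of at least 1 in size and an interval that excluded 0. A count of 0 entered as 3 counts, and no gene past the rule had a 0 in either library. The rule, the gene lists, the alternatives and the rule for named genes were set before the data were examined. Named genes are Sparcl1 and Sparc, the 15 higher and 15 lower genes whose interval bound nearest 0 lies farthest from 0 (predicted and clone names left out), the 2 highest and 2 lowest members of each list past the rule, and the most abundant members of primary lists with fewer than 2 such members in a direction. Other members of a list were named as examples after their values were seen. The value of 1 list member is not reported here. The 45 lists held 941 entries, of which 4 were matched by an older symbol and 33 were not in the table used. The primary lists were cartilage matrix, hypertrophy and mineralisation, matrix-degrading proteases, TNF and NF-κB targets, and cytokines and chemokines. A list's median log2 ratio was ranked among 10000 random lists of the same size, matched on mean expression in 20 bins, when at least 5 members were measured, and a list stood apart below percentile 2.5 or above 97.5. This describes the libraries and does not test the treatment.

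The steps were tested on simulated data drawn for the comparison of Sparcl1 with PBS. With 100 genes changed by a log2 of 1.5 and 100 by 2, 98% and 96% were recovered in their direction, 31 of 13115 unchanged genes passed the rule, and 95.5% of intervals over 13311 genes held the true ratio. These simulated libraries held counting error only, with no variation between cultures. The figures therefore check the steps and do not give the rule's accuracy on real cultures. For each assumed coefficient of variation (0.1, 0.2 and 0.4), 20 pairs of unchanged libraries were simulated. Alternatives were total counts, DESeq2 1.42.0 size factors and upper-quartile factors for scaling, no count filter or at least 100 summed counts, ratios of 1.5-fold and 3-fold, intervals widened by an assumed variation, leaving out predicted and clone names, a prior count of 2, 5 or 50 expression bins, list means, list members held by no other list, and removal of smooth trends (lowess, span 0.3) on expression or exon length. Removal of a GC trend, alone and with length, was added after seeing the data, because log2 ratios rose with GC content across genes (Spearman rho 0.35) and fell with exon length (-0.26). These are correlations across genes, which are not independent replicates.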

Results

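Gene expression was measured by RNA sequencing in primary mouse chondrocytes, the cells that make and maintain cartilage, cultured from wild-type animals. One culture condition received phosphate-buffered saline (PBS) as a control, and the other received recombinant mouse Sparcl1 protein at 50 ng/ml, each for 3 days. Sparcl1 is a secreted matricellular protein related to Sparc. The question the design poses is which genes differ in chondrocyte cultures exposed to added Sparcl1. Several macrophage marker genes were abundant in both libraries, such as Lyz2 (39139 and 44617 counts) and Csf1r (10176 and 9091). Others were rare, such as Aif1 (54 and 40). A difference in these bulk libraries therefore need not come from the chondrocytes. There was 1 library per group. The control library held 29858851 gene counts and the Sparcl1-treated library 26871933. At least 1 count was seen for 15497 genes in the control and for 15407 genes after Sparcl1. The 10 most abundant genes took 11.8% and 10.6% of the counts, and mitochondrially encoded genes 1.87% and 1.83%. No difference given here has a replicate check, so genes are called higher or lower by a rule of size, and every interval covers at most the counting error of reads. Ratios are Sparcl1-treated over control.

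In the Sparcl1-treated library, the matrix-degrading enzyme stromelysin 1, encoded by Mmp3, stood at 438 CPM (counts scaled to a common library size) against 104 in the control. Several inflammatory chemokine genes were also higher, although the list of cytokines and chemokines did not stand apart by its median (log2 0.11, percentile 97.3). Ccl5, which attracts T cells and monocytes, was 4.44-fold higher. The neutrophil-attracting chemokine genes Cxcl2, Cxcl3 and Ppbp were 4.46-fold, 2.94-fold and 2.32-fold higher. The Cxcl2 ratio is poorly fixed, from 9 and 37 counts (log2 2.16, 95% counting interval 1.08 to 3.39). Another chemokine gene, Cxcl15, was 4.43-fold lower, from 24 and 5 counts. Genes of the interferon response were lower: Ifit1, an antiviral RNA-binding protein, was 2.92-fold lower, and Isg15, a ubiquitin-like modifier, was 2.43-fold lower. Cartilage matrix genes such as Col2a1, the main cartilage collagen, were slightly lower as a list, with a median log2 ratio of -0.20. Of these 26 genes 21 had ratios below 1, and none passed the rule of size.

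Of 13317 genes with at least 20 summed counts, 127 (0.954%) were higher and 126 (0.946%) were lower in the Sparcl1-treated library by the rule of size, which asks for a log2 ratio of at least 1 in size and a 95% counting interval that excludes 0. Most of these genes had few reads: 107 of the higher and 88 of the lower genes had fewer than 100 summed counts. With at least 100 summed counts, 20 genes were higher and 38 lower. Across the 11194 genes with at least 200 summed counts, the central 95% of log2 ratios ran from -0.42 to 0.42. In simulated pairs of unchanged libraries the rule took a median of 22 higher and 25 lower genes at an assumed biological coefficient of variation of 0.1, but 178 and 175 at 0.2. The observed counts lie above the simulated ones at 0.1 and below those at 0.2. With at least 100 summed counts, the simulated medians were 1 higher and 1 lower at 0.1, with at most 3 and 4. At 0.2 they were 118 and 118, so the 20 and 38 observed again lie between. Each simulation gave all genes the same variation, and 1 library per group gives no estimate of that variation. A larger variation in all genes would also widen the central 95% of log2 ratios. The simulated ratios were not compared with the observed -0.42 to 0.42 in that respect. These counts therefore do not show which variation applies, nor whether the genes past the rule reflect ordinary variation.

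**Figure D1:**
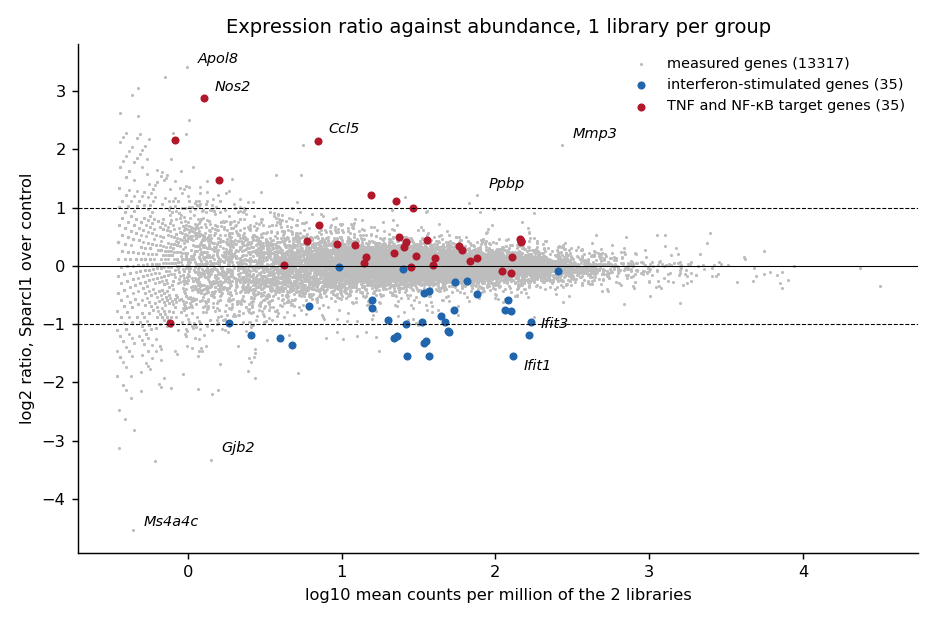
Log2 ratio of Sparcl1-treated over control (vertical axis) against the log10 mean CPM of both libraries (horizontal axis), with 1 point per measured gene and dashed lines at a log2 ratio of -1 and 1. The 35 interferon-stimulated genes (blue) all lie below 0, from -1.55 to -0.02, while TNF and NF-κB target genes (red) lie mostly above 0, and Mmp3 stands apart among abundant genes at 2.07.

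Sparcl1 itself had 289 counts in the control and 208 in the treated library, a log2 ratio of -0.36 (95% counting interval -0.62 to -0.10), so the transcript of the added protein was present at a low level in both cultures. Sparc, the related collagen-binding glycoprotein also called osteonectin, was far more abundant, with 151054 and 116485 counts and a log2 ratio of -0.26 (-0.27 to -0.25). Of the 6 measured SPARC family genes none passed the rule of size and 5 had ratios below 1, with a median log2 ratio of -0.21 (percentile 0.92 among matched random lists), though the list did not stand apart by its mean (-0.18). In the GRCm38 (mm10) assembly, Sparcl1 lies on chromosome 5 at 104079111 to 104113733. The bone and mineralisation genes Ibsp (104299171 to 104311469) and Spp1 (104435118 to 104441050) lie close by on the same chromosome.

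Among the 15 highest named genes, Apol8, a member of the apolipoprotein L family, had the largest ratio, with 5 counts in the control and 49 after Sparcl1 (log2 3.41, 2.09 to 5.10). Nos2, the inducible nitric oxide synthase, had 9 and 61 counts (2.88, 1.86 to 4.07), and Acod1, which makes the immune metabolite itaconate, had 9 and 47 (interval 1.46 to 3.72). Mmp3 combined a large ratio with high abundance, at 3078 and 11906 counts (2.07, 2.01 to 2.13). Serpinb2, an inhibitor of plasminogen activators, had 64 and 247 counts (2.07, 1.66 to 2.49). Sema6a, a transmembrane semaphorin, and Slitrk2, a neuronal transmembrane protein, were higher from only 3 control counts each, to 23 and 21. The remaining higher genes of this set were Mmp10, Tarm1, Sncg, U90926, Ccl5, Cxcl2, Cxcl3 and Ppbp. Of these, Tarm1, a receptor of myeloid cells, had 8 and 36 counts, Sncg, which encodes gamma-synuclein, had 4 and 22, and U90926 had 81 and 221.

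Among the 15 lowest named genes, 6 were on the list of interferon-stimulated genes. Gjb2, which encodes the gap junction protein connexin 26, had 76 counts in the control and 7 after Sparcl1 (log2 -3.32, -4.69 to -2.21). Agtr1a, an angiotensin II receptor, had 33 and 3 counts (-3.34, -5.69 to -1.67), and Ms4a4c had 25 and 1 (-4.53, -9.89 to -1.92), so the size of both differences is poorly fixed. Eln, which encodes elastin, had 76 and 16 counts (-2.13, -3.01 to -1.34). Cyp1a1, a classic target of the aryl hydrocarbon receptor, had 113 and 30 (-1.80, -2.43 to -1.20). Ifi209, Ifi206, Iigp1 and Ifitm1, all known as interferon-inducible but not on the fixed list, had log2 ratios of -1.84, -2.20, -1.46 and -2.11.

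**Figure D2:**
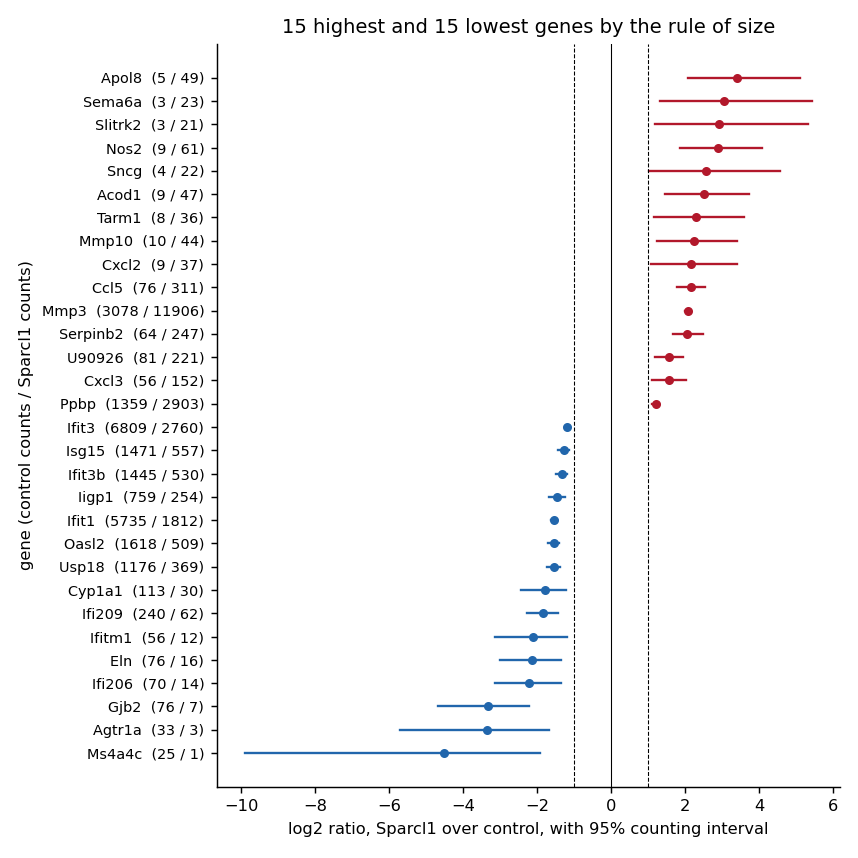
Log2 ratio of Sparcl1-treated over control (horizontal axis, points) with its 95% counting interval (lines) for the 15 highest (red) and 15 lowest (blue) genes by the rule of size, with control and treated counts beside each symbol. Intervals are narrow for Mmp3 (2.01 to 2.13) and Ifit1 (-1.62 to -1.47) and wide for genes with few counts such as Ms4a4c (-9.89 to -1.92).

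Genes of the interferon response, which cells switch on against viruses, were lower as a group. Of 35 measured list members 13 were lower by the rule of size and none was higher, against 0.33 expected in each direction for a random list of this size, not matched on expression. The median log2 ratio was -0.96, below all 10000 random lists of matched expression (percentile 0). All 35 ratios lay below 1, or 34 when total counts served as library sizes. Ifit1 had 5735 and 1812 counts (-1.55, -1.62 to -1.47) and Ifit3 had 6809 and 2760 (-1.19, -1.25 to -1.12). Usp18, which strips Isg15 from proteins, and Oasl2, of the oligoadenylate synthetase family, were both at -1.55. Rsad2 (viperin), Mx1, Mx2, Oas3, Gbp3, Ifi44, Ifit3b, Isg15 and Irf7, the master factor of type I interferon genes, were also lower, from -1.36 to -1.12. Bst2, which tethers budding virus to the cell surface, had a log2 ratio of -0.78 and did not reach the size set. At the other end of the list, Ifi27, Psmb8 and Psmb9 were at -0.09, -0.05 and -0.02. Antigen presentation genes, several of them interferon-responsive, had a median of -0.01 over 16 genes (percentile 52.3), with none past the rule. Ifit3 (chromosome 19, 34583531 to 34588731), Ifit3b (34607970 to 34613401) and Ifit1 (34640871 to 34650009) are neighbouring, similar genes, and their values are uncertain where counting split reads between copies. The same holds for the Oas, Gbp and Ifi200 families.

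Targets of tumour necrosis factor (TNF) and NF-κB, the main transcription factor of inflammation, were higher as a group. Of 35 measured genes 6 were higher by the rule of size and none was lower, against 0.33 expected in each direction at random. That expectation was not matched on expression, and 107 of all 127 higher genes had fewer than 100 summed counts, as did Nos2, Cxcl2 and Il6 here. The median log2 ratio was 0.36, above all 10000 matched random lists (percentile 100), and 31 of 35 ratios were above 1 (32 with total counts as library sizes). The 6 higher genes were Nos2, Cxcl2, Ccl5, the inflammatory cytokine gene Il6 (25 and 64 counts, log2 1.47), the neutrophil chemokine gene Cxcl1 (275 and 590, 1.22) and the monocyte chemokine gene Ccl2 (422 and 841, 1.11). The most abundant targets did not reach the size set: Icam1, an adhesion molecule, was at 0.45, Tnfaip2 at 0.43, the acute-phase gene Saa3 at 0.42 and complement component C3 at 0.41. Nfkbia, the feedback inhibitor of NF-κB, was at 0.44 and Tnf itself at 0.43. Cd40 (-0.98) and Vcam1 (-0.11) had ratios below 1. Macrophage markers had a median log2 ratio of 0.03 over 19 genes (percentile 82.3), with the abundant lysozyme gene Lyz2 at 0.31, Itgam at 0.45, Csf1r at -0.05 and Fcgr1 at -0.61.

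Cytokine and chemokine genes included 7 higher and 1 lower among 29 measured members. Of the higher members, Ccl5, Cxcl1, Cxcl2, Il6 and Ccl2 are the same genes counted above on the TNF and NF-κB list. The others were Cxcl3 (56 and 152 counts, log2 1.56) and Tnfsf11 (21 and 42, 1.12), which encodes RANKL, the factor that drives osteoclast formation. Cxcl15 was the lower member, with 24 and 5 counts (-2.15, -3.89 to -0.73). The list median was 0.11 at percentile 97.3, just short of the upper limit, while its mean of 0.40 lay past it. By members in no other list the median was 0.08 (percentile 92.6). Among the most abundant members, Csf1, the macrophage growth factor, was at 0.06 with 53510 and 51556 counts, and Tnfrsf11b, the RANKL decoy receptor osteoprotegerin, at 0.01. Cxcl12 was at -0.27 and Cx3cl1 at 0.15, while Cxcl5, with 1955 and 3550 counts, was at 0.98. Ppbp, Cxcl3, Cxcl15 and Cxcl2 lie in a chemokine cluster on chromosome 5 between 90768518 and 90905938, where Cxcl15 was lower and the other 3 were higher.

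Matrix-degrading proteases as a group stayed near equal expression, with 2 of 29 measured members higher and none lower, and a median log2 ratio of 0.01 (percentile 67.6). The 2 higher genes were the stromelysins Mmp3 (chromosome 9, 7445822 to 7455975) and Mmp10 (7502352 to 7510240; 10 and 44 counts, log2 2.25, 1.24 to 3.41). Mmp13, the main collagenase of cartilage, lies beside them at 7272514 to 7283331 and had 9241 and 8544 counts, a log2 ratio of 0.00 (-0.04 to 0.05). The aggrecanase genes Adamts5 and Adamts4 were at 0.04 and -0.30, and the cathepsin genes Ctsb and Ctsl at 0.03 and 0.01. The list mean of 0.15 lay past the limit where the median did not (percentile 98.8). Among 12 protease inhibitors none passed the rule and the median was 0.04 (percentile 87.1; 0.11 and 99.1 by members in no other list), with Timp1, an inhibitor of metalloproteinases, at 0.53 with 30427 and 40561 counts.

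Cartilage matrix genes had slightly lower levels in the Sparcl1-treated library as a list, although none of 26 members passed the rule of size. The median log2 ratio was -0.20 (percentile 0), and 21 of 26 ratios lay below 1. Col2a1 had 254556 and 199410 counts (log2 -0.24, -0.24 to -0.23), the proteoglycan gene Bgn 153798 and 125376 (-0.18), and Fmod 170702 and 143553 (-0.13). Acan, which encodes the main cartilage proteoglycan aggrecan, was at -0.50, Col11a1 at -0.37 and Chad at -0.86, whereas Prelp was at 0.15 and Prg4, the joint lubricant lubricin, at 0.39. Chondrocyte transcription factors and receptors had a median of -0.13 over 14 genes (percentile 1.13), with the cartilage master regulator Sox9 at -0.24 and Fgfr3 at -0.37, but the list did not stand apart by its mean (-0.01, percentile 49.2), with the length trend removed alone (percentile 8.70) or with a GC trend (-0.08), or by members in no other list (-0.13, percentile 2.88).

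Genes of chondrocyte hypertrophy and mineralisation, the late stage at which cartilage turns to bone, had a median log2 ratio of -0.16 over 18 members (percentile 0.19). Phospho1, a phosphatase of matrix vesicles, was the 1 higher member, with 10 and 27 counts (1.55, 0.46 to 2.76), and none was lower. The bone sialoprotein gene Ibsp was at -0.62 (4008 and 2399 counts), the alkaline phosphatase gene Alpl at -0.54 and Panx3 at -0.68. Spp1, which encodes osteopontin, went the other way at 0.56 (59409 and 80589 counts), and Col10a1, the marker collagen of hypertrophy, was at 0.05. The list did not stand apart by its mean (-0.10) or when restricted to members held by no other list (-0.03). Osteoblast markers, which share Ibsp, Alpl, Bglap, Sp7 and Dlx5 with it, had the lowest median of any cell type list, -0.40 over 12 genes (percentile 0), with the bone collagen gene Col1a1 at -0.38 and Omd at -0.62. Over osteoblast markers in no other list the median was -0.34 (percentile 1.65).

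Cell cycle genes were slightly more abundant as a list in the Sparcl1-treated library. None of 39 measured proliferation genes passed the rule, the median log2 ratio was 0.25 (percentile 100), and 38 ratios were above 1 (37 to 39 under the other scalings). The DNA replication licensing gene Cdc6 was at 0.52, the mitotic kinase gene Aurka at 0.49, Rrm2 at 0.42, and the marker Mki67 at -0.02. Hypoxia and glycolysis genes had a median of 0.21 over 28 genes (percentile 100), with the glycolytic enzyme genes Pkm at 0.39 and Ldha at 0.20. Antioxidant genes of the NRF2 pathway had a median of 0.19 over 22 (percentile 100), with the quinone reductase gene Nqo1 at 0.42 and the haem oxygenase gene Hmox1 at 0.32. No member of either list passed the rule. Contractile and smooth muscle genes had a median of -0.24 over 13 genes (percentile 0.01), with Acta2, smooth muscle actin, at -0.65 and Tagln at -0.52. Fibroblast and dedifferentiation genes had a median of -0.16 over 22 (percentile 0.01), with periostin (Postn) at -0.51 and Col1a2 at -0.30. Tendon and ligament markers had a median of -0.25 over 8 (percentile 0.12), and Tnmd, the tendon gene tenomodulin, was lower, with 105 and 48 counts (-1.01, -1.54 to -0.51). By its mean (-0.26) the tendon list did not stand apart.

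Shifts under 0.10 in size were seen for p53 target genes (median 0.08 over 20, percentile 98.5), complement and acute phase genes (0.09 over 17, 98.8), nuclear oxidative phosphorylation genes (0.08 over 36, 99.6) and cytosolic ribosomal protein genes (0.07 over 49, 99.8). The complement list held 1 lower gene, C2 (42 and 15 counts, log2 -1.37). With GC and length trends removed, the complement, oxidative phosphorylation and ribosomal lists no longer stood apart, at 0.07, 0.04 and 0.02, nor did they with the length trend alone removed. The p53 list did not by its mean (0.08), with the length trend removed (0.07) or by members in no other list (0.08), and the complement list also did not by its mean (0.07) or by members in no other list (0.08). In all, 17 of 40 lists with enough measured members stood apart, 8 above and 9 below. By chance 2.0 would, if genes within a list varied independently of each other. Genes regulated together can shift together between any cultures, so the excess over 2.0 is not evidence of a treatment effect.

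**Figure D3:**
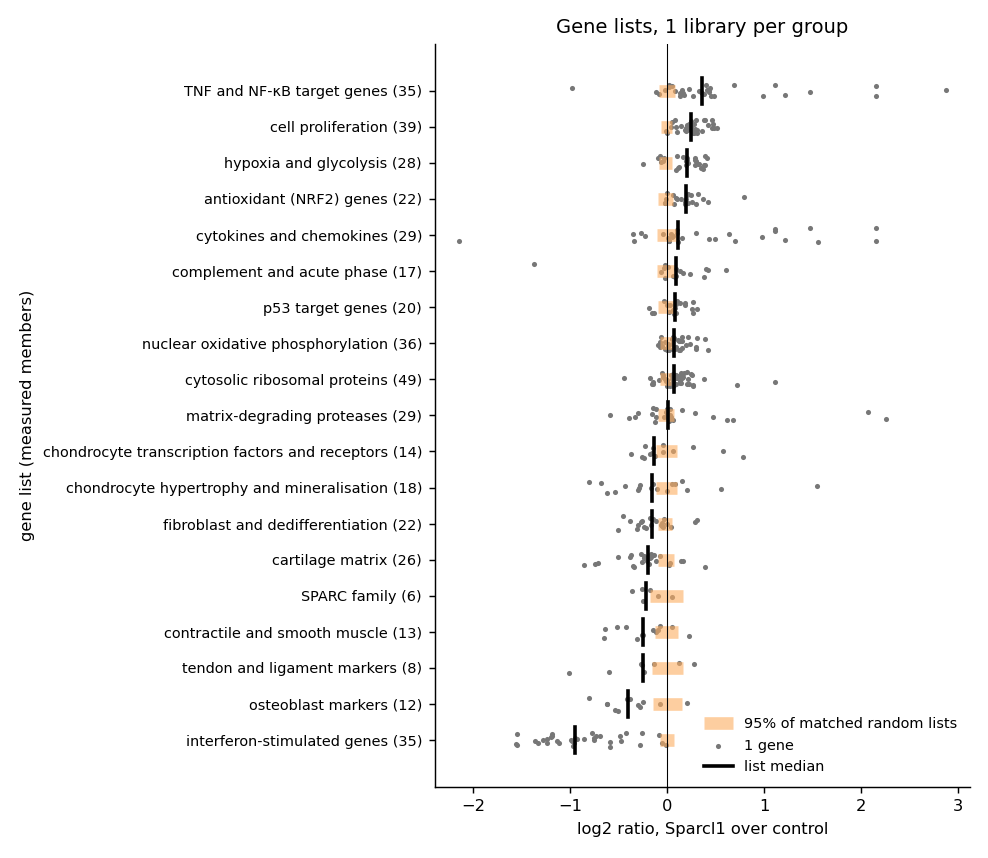
Log2 ratio of Sparcl1-treated over control (horizontal axis) for the members of each gene list (grey points), with list medians (black bars) and the central 95% of medians of 10000 random lists matched on expression (orange), for the lists that stood apart and the lists set as primary. Interferon-stimulated genes have a median of -0.96, TNF and NF-κB target genes 0.36, and the other lists lie between -0.40 and 0.25.

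The remaining pathway lists did not stand apart from random lists by their medians without a correction. Signalling and stress lists had medians of 0.08 for senescence and cell-cycle arrest (18 genes), 0.07 for apoptosis (18), -0.00 for TGF-β and BMP targets (25), 0.02 for Wnt targets (18), -0.06 for Notch targets (9), 0.08 for growth factors (19), 0.05 for immediate-early genes (26), -0.07 for the unfolded protein and integrated stress response (24) and 0.07 for heat shock (14). Cholesterol and fatty-acid synthesis genes were at -0.06 (27), mitochondrially encoded genes at 0.02 (11) and histone genes at 0.04 (10). The median and mean had opposite signs for Notch targets (mean 0.22), Wnt targets (-0.04) and immediate-early genes (-0.00). Some of these lists did pass the limits in other settings: senescence by its mean (0.27, percentile 99.99), to which Mmp3 and Il6 add most, and with the expression (0.10) or GC trend (0.10) removed, heat shock by its mean (0.10) and with the GC trend removed (0.08), and the unfolded protein list with the length trend removed (-0.10, percentile 0.24). In the settings added after seeing the data, the GC trend removed alone or with length, so did the unfolded protein list (-0.09 and -0.10), growth factors (0.13 and 0.10), TGF-β and BMP targets (-0.08 and -0.09) and cholesterol and fatty-acid synthesis (-0.08 both ways), and with GC alone mitochondrially encoded genes (0.13). The senescence list held 2 higher genes, Mmp3 (2.07) and Il6 (1.47), which other lists also hold, and by members in no other list its median was 0.07 (percentile 88.0). Other members past the rule were the Notch ligand gene Dll1 (11 and 30 counts, log2 1.56), the Notch target Hey2 (20 and 37, 1.00), the growth factor gene Fgf1 (6 and 21, 1.92) and the immediate-early factor gene Egr3, which was lower with 427 and 164 counts (-1.26). Rpl38 (11 and 22, 1.12), mt-Nd3 (11 and 29, 1.52) and Hist1h3b (6 and 25, 2.18) were higher from few counts and have near-identical copies elsewhere in the genome, so their values are uncertain.

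None of the remaining cell type lists stood apart, except pericyte markers once a GC trend was removed (-0.19, percentile 2.33). Medians were 0.01 for synovial fibroblasts (10 genes), 0.03 for osteoclasts (9), 0.04 for endothelial cells (8), -0.13 for pericytes (6), -0.15 for adipocytes (5) and -0.11 for neural and Schwann cells (8). The mean had the opposite sign for osteoclasts (-0.03), adipocytes (0.00) and neural cells (0.03). Too few members were measured for a percentile in skeletal muscle (3 genes, median -0.08), epithelial cells (2, 0.14), and lymphocytes and granulocytes (2, 0.04), where the neutrophil alarmin gene S100a8 was higher with 15 and 31 counts (1.16). No erythroid marker was measured. The 4 Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had log2 ratios of -0.22, -0.25, -0.25 and -0.22, with a median of -0.23 that became -0.11 with GC and length trends removed.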

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

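Both gene counts moved with the thresholds and much less with scaling. Against 127 higher and 126 lower genes, at least 100 summed counts gave 20 and 38, 1.5-fold gave 309 and 313, 3-fold gave 44 and 36, and intervals widened by an assumed variation of 0.4 gave 19 and 18. No filter on low counts gave 201 higher genes. These changes follow from how each setting is built. In the other 19 settings of the counts they stayed within 1.5 times. Medians of TNF and NF-κB targets and of cartilage matrix genes kept their direction and stood apart in every alternative run, as did that of interferon-stimulated genes. The hypertrophy list did not stand apart by its mean (-0.0981) or by members in no other list (-0.0262). The protease list stood apart by its mean alone (0.1529). The cytokine list stood apart with no filter (0.1172), at least 100 summed counts (0.1057), 5 bins (0.1086), its mean (0.4005), the expression trend removed (0.1102) and, in a setting chosen after seeing the data, the GC trend removed (0.1239). The cause was not tested for these lists. Over all lists, 475 settings left the call as it was, 24 in 11 lists brought a list past the limit and 19 in 8 lists ended it, and no result that stood apart or passed the rule changed direction. Named genes stayed within their counting interval in 245 settings, and the other 11 were shifts of 0.03 under total counts, in genes whose intervals are narrow. Depth limits genes with few counts most. Leaving out a replicate was not possible with 1 library per group. No paired analysis was possible because each group has 1 library.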

Other observations

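Several genes with at least 100 summed counts differed by the rule of size but lie outside the rule for named genes, and were chosen after their values were seen. Mt2, which encodes the metal-binding protein metallothionein 2, had 1267 counts in the control and 2474 after Sparcl1 (log2 1.08, 0.98 to 1.18), and the zinc importer gene Slc39a4 had 32 and 72 (1.29, 0.67 to 1.94). Angptl4, a secreted inhibitor of lipoprotein lipase, had 466 and 971 counts (1.18, 1.02 to 1.34). S100a7a, of the S100 calcium-binding proteins, had 433 and 869 (1.12, 0.95 to 1.29), and Flt4, a receptor for lymphatic growth factors, had 96 and 190 (1.10, 0.74 to 1.47). The chemokine gene Cxcl5, beside Ppbp in the chromosome 5 cluster, had 1955 and 3550 counts, a log2 ratio of 0.98 that fell just short of the size set.

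Among lower genes chosen in the same way, Trim30a had 1233 and 564 counts (log2 -1.01, -1.16 to -0.87), Phf11d had 697 and 275 (-1.22, -1.43 to -1.02), and Oas1g had 117 and 40 (-1.43, -1.99 to -0.90). St8sia2, which adds polysialic acid to proteins, had 327 and 128 counts (-1.24, -1.54 to -0.94), the homeobox gene Meox1 had 118 and 37 (-1.56, -2.13 to -1.01), and Car3, a carbonic anhydrase, had 116 and 34 (-1.65, -2.25 to -1.09). Ifnb1, Ifng, Ifna1, Ifna2 and Ifna4, which encode interferons, had 0 counts in both libraries, which allows up to 0.102 CPM in the control and 0.110 CPM in the treated library.

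All tests in this part were chosen after the list medians and the trends on GC content and length had been seen. For the lower interferon-stimulated genes, the list median stayed at -0.93 (-0.9291) with trends on GC content and exon length removed. Those trends were small: median log2 ratios were -0.10 and 0.09 in the lowest-GC and highest-GC sixths of genes, and 0.07 and -0.08 in the shortest and longest. Removing them could hardly move this list, so the outcome shows only that trends of this size do not account for its shift. Fewer cells of another type would lower all of that type's markers as much as the interferon list (median -0.96). Yet the lowest cell type median was -0.40 (-0.3987, osteoblast markers). Types with under 5 measured markers or with no list were not covered. The 16 members from no multigene family had a median of -0.91 (-0.9071), which argues against reads shared between gene copies. A lower interferon response in the treated culture is a hypothesis that these tests leave standing, but whether the added protein or a difference between the cultures brought it stays open.

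For the higher TNF and NF-κB targets, the list median was 0.36 (0.3630) with both trends removed. Here too the trends were too small to move the list far, so this shows only that they do not account for its shift. More macrophages in the treated culture would raise their markers at least as much as that list, yet 15 macrophage markers on no inflammatory, antigen presentation or protease list had a median of 0.03 (0.0295, SD across genes 0.28). Lymphocytes and granulocytes, with 2 measured markers, were not covered. A change of state in macrophages already present may also raise these targets and was not tested. Sparcl1 treatment and a difference between cultures cannot be told apart with 1 library per group. A trace of another agent in the added protein also stays open and was not tested.

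For the small shifts of whole lists, 15 lists stood apart with medians under 0.5 in size, leaving out TNF and NF-κB targets, and 11 of these still did, in the same direction, with GC and length trends removed. That argues against the joint trend as the whole cause, although across genes the lowest-GC sixth had a median log2 ratio of -0.10 and the highest-GC sixth 0.09. Treatment, or a difference between cultures in growth or density, may underlie the remainder and was not tested.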
